A study of Rattus norvegicus with 151 samples.

How the data were processed

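Expression was measured on Affymetrix Rat Genome 230 2.0 arrays from biotin-labelled total RNA of liver and kidney, with 1 array per tissue sample. The authors named RMA as the processing, which gave background corrected, quantile normalized log2 values for each of 31099 probe sets, and these deposited log2 values were used as they stood. The version of RMA, the software and whether the tissues or the chemical sets were processed together were not stated. The array annotation used here named 21268 probe sets, of which 20832 carried 1 gene symbol, 436 carried several and were not used, and 9831 were unnamed here and not used. The symbols stood for 14218 genes. Array medians lay between 5.215 and 5.376 log2 units, and each array's median correlation with the others of its tissue and chemical set lay between 0.987 and 0.995. For arrays the number per group sets the precision.

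The column of 1 kidney (0.1 mg/kg MCHM, replicate 13) was left out. Its values correlated with those of the other kidneys at a median r of 0.401 as deposited and of 0.952 after all its values were moved by 1 position, where the lowest other kidney array had 0.986, so its values did not stand beside their own probe set names.

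For each gene the probe set with the highest mean over the arrays of the tissue was kept. A gene was tested where its value was above the 40th percentile of all values of the tissue (4.69 log2 units in liver, 4.66 in kidney) in at least 3 arrays of the fit. Models were fitted with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8), using lmFit and eBayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. limma's tests were two-sided. Each dose was compared with the vehicle group of its own set in 6 separate fits, 1 per tissue and chemical. The dose trend was a linear contrast on the rank of the dose with the vehicle as rank 0. Differences between chemicals at a matched dose were tested as the difference of both dose-minus-vehicle contrasts in a fit of all groups of a tissue, which also gave the comparisons of vehicle groups. The tissue difference at 500 mg/kg was tested the same way in a fit of both tissues per chemical. Intervals are 95% intervals from these fits.

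Gene lists (21 pathway lists and 12 lists of cell type markers) were tested with camera in limma at a preset correlation of 0.01 between genes, where at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data. Counts of members past the threshold were made over all genes tested and also with the adjustment over the list alone. The comparisons, the filter, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

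Genes were named by a rule. At the highest dose of each chemical in each tissue, the rule took the 10 largest rises and the 10 largest falls among called genes whose treated arrays all lay on the same side of the vehicle mean, and up to 4 members of each list with the smallest adjusted p. For differences between chemicals at 500 mg/kg and between tissues it took the 5 largest in each direction. Genes without an assigned name were counted but not printed. Values are given as group means with their SD, and changes as differences of log2 means with the SE from limma where one is given.

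Agreement between chemicals was described by Pearson's r and Spearman's rho of log2 changes across genes and by the overlap of called genes. The alternatives were no filter, the mean of all probe sets of a gene, a further quantile normalization, array weights, all chemicals in 1 fit or only the chemicals compared, each array left out in turn, and the replicate number as a block in the tissue comparison. Alternatives added after the data had been seen were the difference between the 5' and 3' beta-actin control probe sets as a covariate, the mean of fat cell markers as a covariate, leaving out the 2 kidneys of the MCHM set highest in those markers or the 3 kidneys of the crude MCHM set lowest in the beta-actin difference, and including the column that had been left out. In tests on simulated data with the layout of each highest dose and 200 changed genes, between 47% and 87% of changes of 0.5 log2 units and between 94% and 98% of changes of 1 were recovered, and false calls were between 2.76% and 8.38% of calls.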

Results

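The series measured messenger RNA with expression arrays in the liver and kidney of male Harlan Sprague-Dawley rats that were given 5 daily doses by gavage. It was part of toxicology work that followed a chemical spill into the drinking water of West Virginia. The chemicals were MCHM (4-methylcyclohexanemethanol), crude MCHM (the technical mixture, mostly MCHM) and PPH (propylene glycol phenyl ether), each with its own corn oil vehicle group. Both MCHM and crude MCHM were given at 500, 300, 100, 10, 1 and 0.1 mg/kg, and PPH at 1000, 500, 100, 10 and 1 mg/kg. Of 151 arrays, 150 were used, 81 from liver and 69 from kidney, in 40 groups of 2 to 5 arrays. An array of the crude MCHM or PPH set is named below by the end of its label, which gives the chemical and the replicate number, and an array of the MCHM set by its replicate number. In liver each treated group held 4 arrays, except 3 at 0.1 mg/kg crude MCHM, and the vehicle groups held 5 (MCHM), 4 (crude MCHM) and 5 (PPH). In kidney the vehicle groups held 5, 3 and 5 arrays, and the treated groups held 4, except 3 used at 0.1 mg/kg MCHM, 3 at 500 mg/kg PPH, 2 at each of the 4 lower doses of crude MCHM and 3 at its 300 and 500 mg/kg. The number of arrays per group limited the precision.

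**Figure D1:**
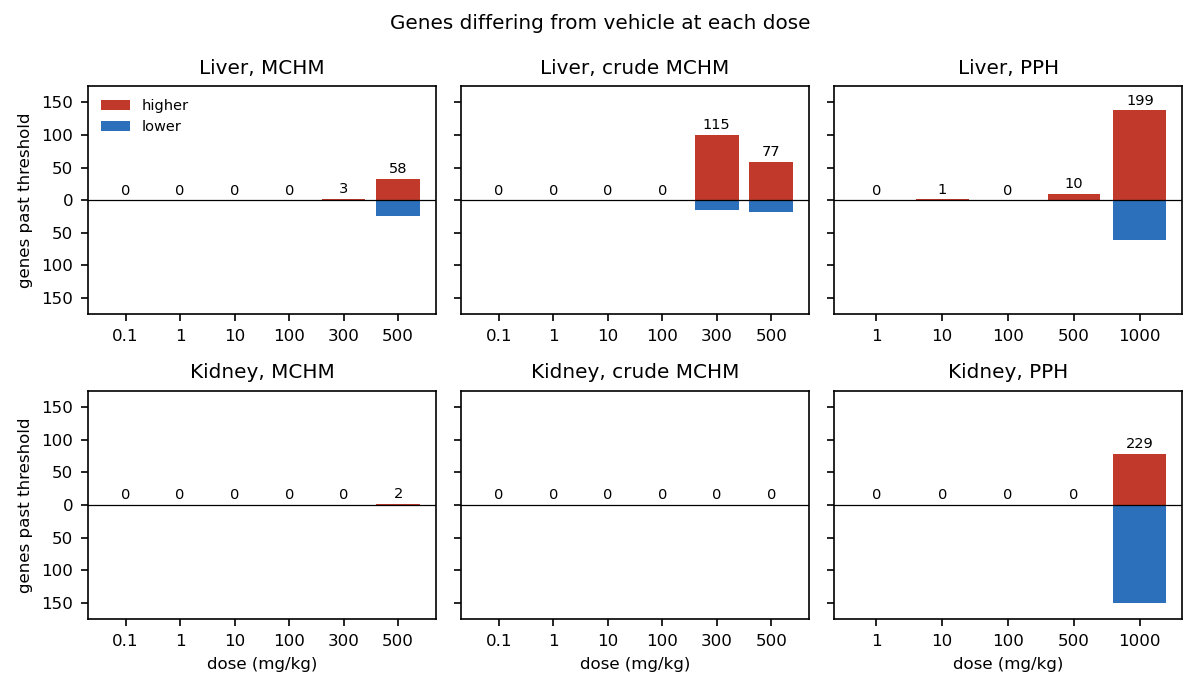
Number of genes that were higher (upward bars) or lower (downward bars) than in the vehicle group at each dose in mg/kg, by tissue and chemical, with the total above each pair of bars. The totals at the highest dose of MCHM, crude MCHM and PPH were 58, 77 and 199 in liver. In kidney they were 2 for MCHM and 0 for crude MCHM, and with PPH 78 genes were higher and 151 lower.

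The first question was which liver transcripts MCHM changed, and from which dose. At 500 mg/kg, 33 genes rose and 25 fell among 11335 tested, and 26 of these changed by at least 1.5-fold. With array weights the count was 173. Gpt, which encodes the transaminase measured in blood as a sign of liver injury, rose 2.32-fold, from 8.57 ± 0.19 (SD, n = 5) to 9.78 ± 0.19 (SD, n = 4) on the log2 scale, with an adjusted p of 0.00272. Tat, the tyrosine aminotransferase, rose 2.62-fold, from 8.67 ± 0.30 (SD, n = 5) to 10.05 ± 0.51 (SD, n = 4), with an adjusted p of 0.0298. Cyp3a23-3a1, a drug-metabolizing cytochrome P450, rose from 12.5 ± 0.13 (SD) to 13.08 ± 0.07 (SD), adjusted p 0.00272. For every gene past the threshold that is named here at a highest dose, all treated arrays of the group lay on one side of the vehicle mean (4 of 4 in each group). For the largest rises and falls the naming rule required this, so it adds no support for them.

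Some fatty acid synthesis genes rose in liver at 500 mg/kg MCHM, and 0 of 8 list calls held with an estimated correlation. The elongase Elovl6 rose by 1.28 ± 0.29 log2 units (SE), the citrate lyase Acly by 0.90 ± 0.19 and the fatty acid synthase Fasn by 0.80. Their adjusted p were 0.038, 0.0272 and 0.0488. The list of 17 genes had a median change of 0.41, with 3 members risen over all genes and 7 when adjusted over the list alone, and passed the list test (adjusted p = 1.37e-06, and adjusted p = 0.186 with an estimated correlation). In the cholesterol synthesis list the sterol reductase gene Tm7sf2 rose from 10.47 ± 0.12 to 11.23 ± 0.20 (SD), adjusted p 0.00272. It was the 1 of 20 members to rise (4 when adjusted over the list alone), and the list median was 0.31 (adjusted p = 6.74e-09, and adjusted p = 0.251 with an estimated correlation). Insig1, which holds back the sterol sensor, was at 0.94 with an adjusted p of 0.102. Among 18 targets of the drug-sensing receptors CAR and PXR, Cyp3a23-3a1, the carboxylesterase Ces2c (0.81 ± 0.15, SE) and Cyp3a18 (0.61 ± 0.10, SE) rose, and 4 did when adjusted over the list alone. That list had a median of 0.16 (adjusted p = 0.00147, and adjusted p = 0.186 with an estimated correlation). Of 37 genes of fatty acid oxidation, which the receptor PPAR-alpha controls, 3 rose: Cyp4a1 by 0.69, Ehhadh by 0.64 and Eci1 by 0.64. When adjusted over the list alone 3 rose and 3 fell, and the list did not pass (median 0.01, adjusted p = 0.663). The mitochondrial glutathione transferase Gstk1 (0.34) was the 1 of 29 phase II conjugation genes to rise, also when adjusted over the list alone, with a list median of 0.09 (adjusted p = 0.0472, and adjusted p = 0.396 with an estimated correlation). Acsm2 (0.98), Bdh2 (0.80), Spmip11 (0.78) and Hes6 (0.77) were the other large rises.

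The genes that fell in liver with MCHM were of mixed function. Cav2, a membrane protein of caveolae, fell from 8.04 ± 0.15 to 7.19 ± 0.17 (SD), adjusted p 0.00272, and the corticosteroid-binding globulin Serpina6 from 12.31 ± 0.12 to 11.74 ± 0.12 (SD), adjusted p 0.00328. In the cell cycle list the spindle protein Nusap1 (−0.70) was the 1 of 27 members to fall over all genes, and 13 fell when adjusted over the list alone (median −0.36, adjusted p = 5.22e-10, and adjusted p = 0.186 with an estimated correlation). Cdk1 was at −0.97 (adjusted p = 0.0823) and Mki67 at −0.99 (adjusted p = 0.1). None of 12 macrophage markers passed over all genes and 9 fell when adjusted over the list alone (median −0.26, adjusted p = 5.41e-07, and adjusted p = 0.186 with an estimated correlation), with Csf1r, the growth factor receptor of macrophages, at −0.25. The leukocyte genes Clec4a3 (−0.61), Ccl5 (−0.60) and the protease inhibitor gene Slpi (−0.78) fell, as did Tent5c (−0.83), Ube2t (−0.64), Etfbkmt (−0.61), Steap3 (−0.58) and the growth hormone receptor Ghr (−0.30). The kidney injury list (median −0.21, 0 of 17, 3 fallen when adjusted over the list alone, adjusted p = 0.00099, and adjusted p = 0.186 with an estimated correlation) and the fibroblast markers (median −0.20, 0 of 12, adjusted p = 0.0146, and adjusted p = 0.396 with an estimated correlation) were lower too.

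Below 500 mg/kg, MCHM changed few liver transcripts. At 300 mg/kg Tm7sf2 (0.73) and Cyp3a23-3a1 (0.49) rose, and Lmcd1, a cofactor of transcription named after its values were seen, fell by 0.79, with adjusted p of 0.0164, 0.0447 and 0.0164. limma called 0 genes at 0.1, 1, 10 and 100 mg/kg, where 476, 646, 710 and 432 genes had an unadjusted p under 0.05. Across doses the trend rose in 97 genes and fell in 173, and in 136 and 162 when the values were quantile normalized again. The count of 58 at 500 mg/kg was 34, 30, 27 and 19 without vehicle replicates 4, 8, 3 and 7, and 21, 35 and 32 without treated replicates 40, 43 and 42. The trend count of 270 was 158 without replicate 40, and the count at 10 mg/kg was 1 without vehicle replicate 8. At 300 mg/kg the count of 3 was 1 without replicate 37 and 0 without vehicle replicate 8 or 7 or treated replicate 36. Gpt, Ces2c, Cav2, Slpi, Serpina6, Cyp3a23-3a1, Cyp3a18 and Tm7sf2 were the 8 of 28 named genes that passed in all 9 fits with 1 array left out, and 6 of 8 list calls did.

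The same question was asked of crude MCHM in liver. At 500 mg/kg, 59 genes rose and 18 fell among 11402 tested, and 25 changed by at least 1.5-fold. With array weights the count was 194. Cyp3a9, another drug-metabolizing P450, rose 3.36-fold, from 7.82 ± 0.54 (SD, n = 4) to 9.57 ± 0.23 (SD, n = 4), adjusted p 0.00989. Abhd1, a hydrolase, rose from 8.04 ± 0.20 to 8.80 ± 0.10 (SD), adjusted p 2.87e-05, and the fatty acid oxidation gene Eci1 from 11.07 ± 0.20 to 11.94 ± 0.08 (SD), adjusted p 0.000115. The protease inhibitor gene A2m fell from 10.12 ± 0.50 to 8.58 ± 0.30 (SD), adjusted p 0.00695, and the thyroxine-binding globulin Serpina7 from 10.14 ± 0.32 to 8.68 ± 0.35 (SD), adjusted p 0.00336. At 300 mg/kg 100 genes rose and 15 fell (47 and 14 when quantile normalized again, and 43 in all with all chemicals in 1 fit), and Abhd1, Tm7sf2, Fabp7, Nim1k and Ccl5 had passed by that dose.

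Some genes of drug and fatty acid metabolism rose with 500 mg/kg crude MCHM, and no list call was kept with an estimated correlation. Of 18 CAR and PXR targets 5 rose, among them Cyp3a9, Cyp3a23-3a1 (0.65) and Ces2c (0.85), and 6 when adjusted over the list alone (median 0.17, adjusted p = 2.92e-05, and adjusted p = 0.0843 with an estimated correlation). Of 37 fatty acid oxidation genes 4 rose, Eci1 (0.87), Cyp4a1 (0.80 ± 0.15, SE), Ehhadh (0.75) and Decr2 (0.44), and 6 when adjusted over the list alone (median 0.12, adjusted p = 7e-05, and adjusted p = 0.179 with an estimated correlation). The thioredoxin reductase Txnrd1 (0.34) was the 1 of 22 targets of the oxidative stress factor Nrf2 to rise (8 when adjusted over the list alone, median 0.18, adjusted p = 7e-05, and adjusted p = 0.214 with an estimated correlation). Gstk1 (0.35) was the 1 of 29 phase II genes to rise (8 when adjusted over the list alone, median 0.17, adjusted p = 6.12e-05, and adjusted p = 0.103 with an estimated correlation). Tm7sf2 (0.51) was the 1 of 20 cholesterol genes to rise (5 when adjusted over the list alone, median 0.14, adjusted p = 0.00112, and adjusted p = 0.501 with an estimated correlation). The fatty acid synthesis list had 0 of 17 members risen and 1 when adjusted over the list alone (median 0.22, adjusted p = 0.00103, and adjusted p = 0.364 with an estimated correlation). Gpt rose 2.06-fold, Ugt2b34l1 and Hyal3 each by 0.73, Ccdc61 by 0.66 and the acute phase protein gene Orm1 by 0.56.

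The 18 genes that fell with 500 mg/kg crude MCHM were of mixed function. The fatty acid binding protein gene Fabp7 fell from 12.16 ± 0.09 to 11.44 ± 0.08 (SD), adjusted p 0.000115, and the apolipoprotein genes Apoa4 and Apoa1 fell by 0.63 and 0.31. Nim1k (−1.31), Kcnj15 (−0.81), Tmed3 (−0.74), Ccl5 (−0.51) and Cnrip1 (−0.44) fell as well. Jchain (−0.81), the joining chain of secreted antibodies, was the 1 of 10 lymphocyte markers to fall, also when adjusted over the list alone (median −0.17, adjusted p = 0.000765, and adjusted p = 0.0843 with an estimated correlation). Markers of fibroblasts (median −0.29, 0 of 12, 4 fallen when adjusted over the list alone, adjusted p = 8.1e-05, and adjusted p = 0.164 with an estimated correlation), macrophages (median −0.15, 0 of 12, adjusted p = 0.00347, and adjusted p = 0.501 with an estimated correlation) and endothelium (median −0.13, 0 of 10, adjusted p = 0.00785, and adjusted p = 0.228 with an estimated correlation) were lower, and so was the kidney injury list (median −0.16, 0 of 17, adjusted p = 0.0045, and adjusted p = 0.216 with an estimated correlation). The cell cycle list did not pass (median −0.04, 0 of 29, adjusted p = 0.822 with an estimated correlation). Its values ranged widely among the vehicle livers (mean of the list 5.85 ± 0.45, SD, n = 4).

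limma called 0 genes at 0.1, 1, 10 and 100 mg/kg crude MCHM in liver, where 703, 546, 752 and 857 genes had an unadjusted p under 0.05. The dose trend rose in 157 genes and fell in 61. When the values were quantile normalized again, the split at 500 mg/kg moved from 76.6% risen to 61% (61 risen, 39 fallen). The share risen in the trend moved from 72% to 52.9% (128 risen). The count of 77 at 500 mg/kg, 0.675% of the genes tested, was 1.17% of them without vehicle replicate Crude_MCHM-104. It was 23, 40 and 40 without vehicle replicates Crude_MCHM-106, Crude_MCHM-108 and Crude_MCHM-105 and 41 and 28 without treated replicates Crude_MCHM-143 and Crude_MCHM-144. At 300 mg/kg the count of 115 was 59, 59, 3 and 68 without vehicle replicates Crude_MCHM-106, Crude_MCHM-108, Crude_MCHM-105 and Crude_MCHM-104 and 39, 17 and 68 without treated replicates Crude_MCHM-138, Crude_MCHM-134 and Crude_MCHM-135. The trend count was between 84 and 136 without any 1 of replicates Crude_MCHM-106, Crude_MCHM-108, Crude_MCHM-134, Crude_MCHM-143, Crude_MCHM-105, Crude_MCHM-110, Crude_MCHM-144 and Crude_MCHM-114, and the count at 100 mg/kg was 5 without replicate Crude_MCHM-129. Eci1, Cyp4a1, Abhd1, Ehhadh, A2m, Serpina7, Fabp7 and Gstk1 were the 8 of 28 named genes that passed in all 8 fits with 1 array left out, and 9 of 11 list calls did.

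**Figure D2:**
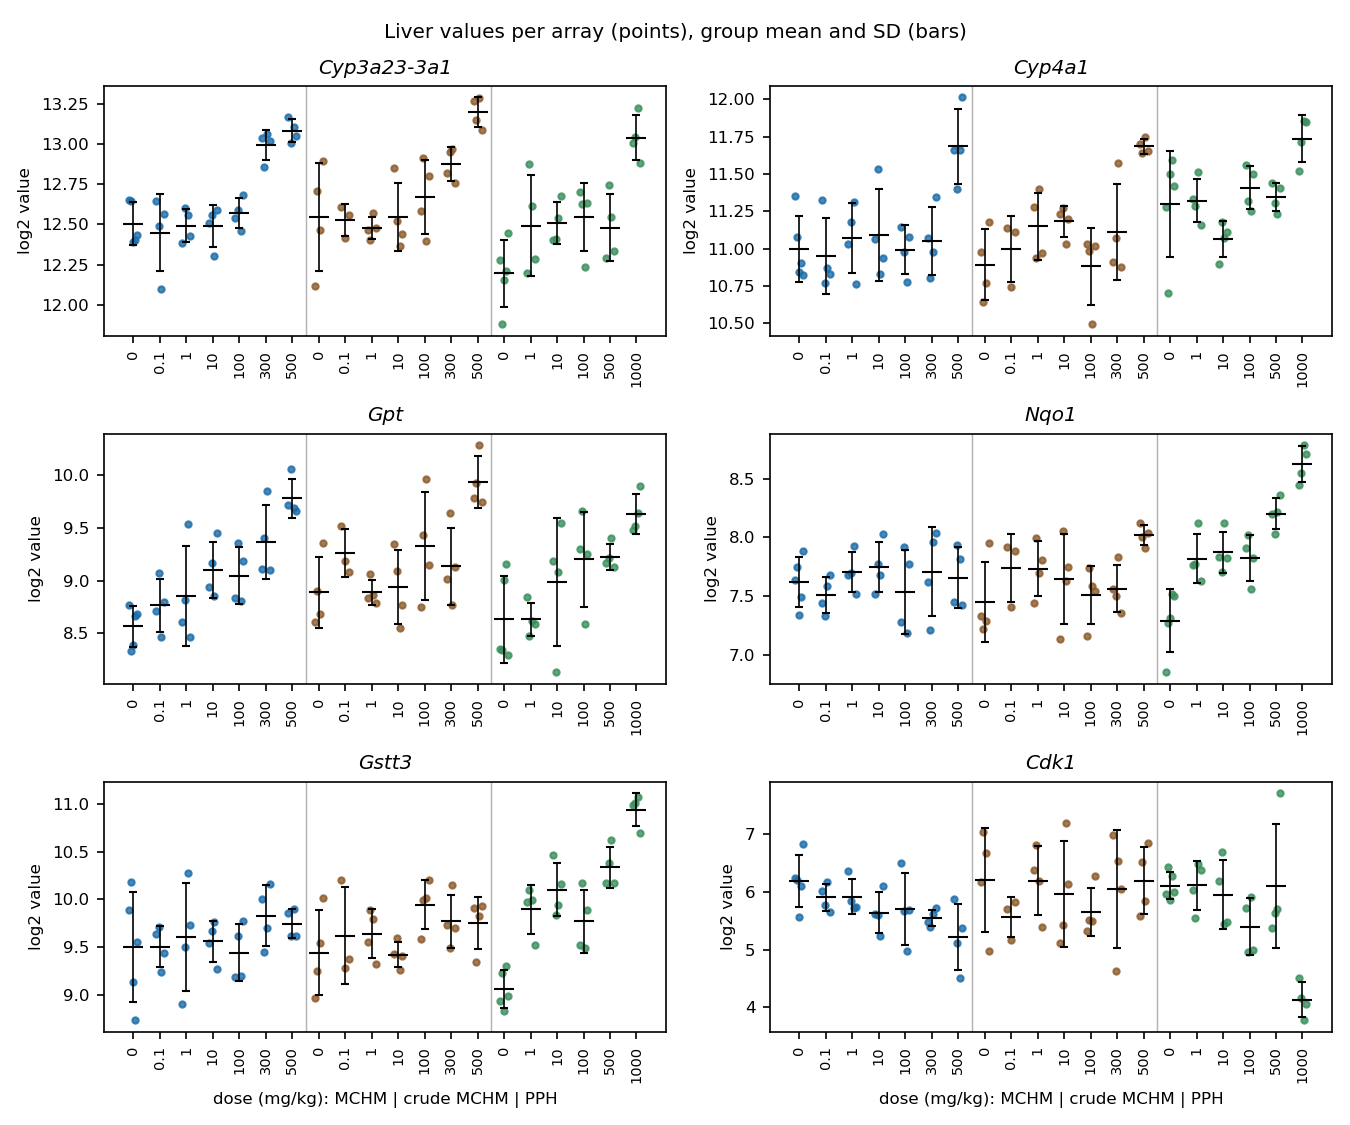
Log2 values of 6 genes in liver, 1 point per array, with the group mean and SD as bars, at each dose in mg/kg of MCHM, crude MCHM and PPH. Mean Cyp3a23-3a1 went from 12.5 in the vehicle group to 13.08 at 500 mg/kg MCHM, and mean Gstt3 from 9.06 to 10.94 at 1000 mg/kg PPH.

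MCHM and crude MCHM were compared at matched doses, because the mixture contains MCHM with other constituents. In liver at 500 mg/kg, 14 genes rose and 3 fell with both, against 0.173 and 0.0399 expected if the calls were unrelated, and 0 moved in opposite directions. The shared risen genes were Abhd1, Ces2c, Cyp3a18, Cyp3a23-3a1, Cyp4a1, Eci1, Ehhadh, Gpt, Gstk1, Mecr, Ociad2, Sqstm1, Tm7sf2 and Uox, and the shared fallen genes were Ccl5, Erlec1 and Serpina6. Across 11269 genes, which are not independent replicates, the changes had r = 0.506 (rho = 0.443) at 500 mg/kg and r = 0.375 (rho = 0.333) at 300 mg/kg. The test of the difference at 500 mg/kg called 0 genes with limma, with 334 at an unadjusted p under 0.05, and the 95% interval lay within 1.5-fold for 79.0% of 11624 genes. For Gpt the difference was 0.17 log2 units (95% interval −0.46 to 0.80), for Abhd1 −0.11 (−0.37 to 0.15) and for Cyp4a1 −0.11 (−0.53 to 0.32). Cyp3a9 (−0.73, interval −1.76 to 0.30), Tat (1.22, interval 0.18 to 2.27) and Nusap1 (−0.81, interval −1.44 to −0.18) stayed open. Each had an adjusted p of 0.997.

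At 0.1, 1, 10, 100 and 300 mg/kg limma also called 0 liver genes between MCHM and crude MCHM, with 526, 426, 639, 376 and 518 at an unadjusted p under 0.05. A count of 1 appeared at 1 mg/kg without MCHM replicate 16 or vehicle replicate 3 or Crude_MCHM-104, at 10 mg/kg without replicate Crude_MCHM-126, and at 300 mg/kg without replicate Crude_MCHM-134.

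**Figure D3:**
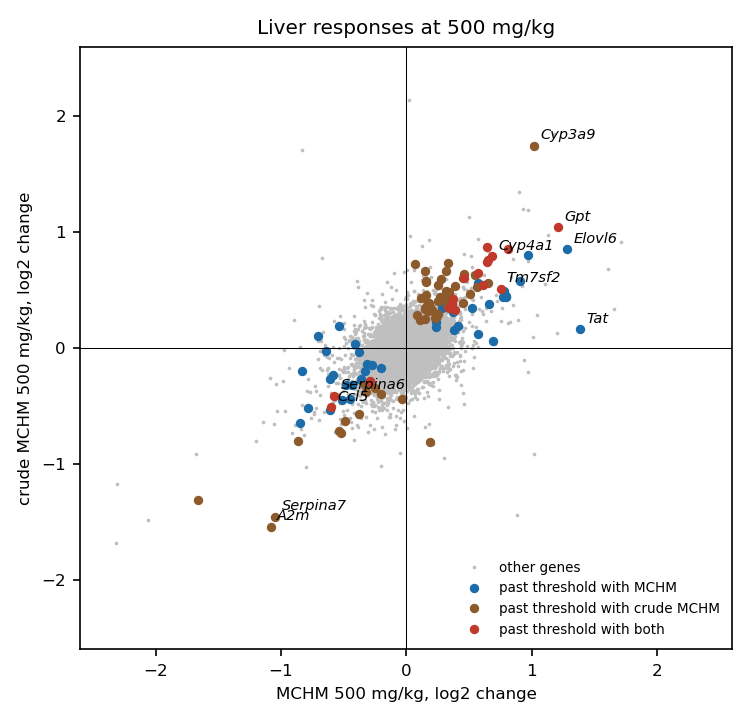
Log2 change from vehicle in liver at 500 mg/kg MCHM (horizontal axis) and 500 mg/kg crude MCHM (vertical axis), 1 point per gene, coloured by which comparison it passed. Across 11269 genes r was 0.506, and 14 genes rose and 3 fell with both.

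The next question was what PPH changed in liver. At 1000 mg/kg, 199 of 11342 genes tested changed, 61 of them downwards and the rest upwards, and 63 changed by at least 1.5-fold. Among the larger rises were Gsta3 and Gstt3, glutathione transferase genes, whose products conjugate reactive compounds. Gsta3 rose 6.27-fold, from 6.77 ± 0.84 (SD, n = 5) to 9.42 ± 0.22 (SD, n = 4), adjusted p 8.74e-05. Gstt3 rose 3.69-fold, from 9.06 ± 0.20 to 10.94 ± 0.17 (SD), adjusted p 2.52e-07. The quinone reductase Nqo1 rose from 7.29 ± 0.27 to 8.62 ± 0.15 (SD), adjusted p 2.72e-06, and the mitotic kinase Cdk1 fell from 6.10 ± 0.23 to 4.13 ± 0.30 (SD), adjusted p 0.00505.

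Detoxification lists were higher with PPH in liver. Of 22 Nrf2 targets 7 rose and 1 fell, with Gsta3, Nqo1, the aldo-keto reductase Akr7a3 (1.27) and the glutathione reductase Gsr (0.72) among the rises, and 11 rose and 1 fell when adjusted over the list alone (median 0.30, adjusted p = 7.53e-11, and adjusted p = 0.0362 with an estimated correlation, so that the call held). Of 29 phase II genes 8 rose, among them Gstt3, Gstt1 (0.53) and Gstp1 (0.49), and 14 when adjusted over the list alone (median 0.15, adjusted p = 7.83e-07, and adjusted p = 0.0362 with an estimated correlation, which held too). Of 19 CAR and PXR targets 7 rose and 1 fell, also when adjusted over the list alone, with the transporter Abcc3 at 1.77, Ces2c at 1.28 and Cyp3a23-3a1 at 0.84 (median 0.33, adjusted p = 1.48e-05, and adjusted p = 0.0614 with an estimated correlation). Of 15 alcohol and aldehyde dehydrogenases 4 rose, including Adh7 (1.5) and Aldh1l1 (0.61), and 1 fell, and the list did not pass (median 0.08, adjusted p = 0.0732).

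Cholesterol synthesis genes rose together at 1000 mg/kg PPH. Of 20 members 13 rose, and 18 when adjusted over the list alone (median 0.69, adjusted p = 4.47e-21, and adjusted p = 0.0614 with an estimated correlation). The squalene synthase gene Fdft1 rose from 10.08 ± 0.16 to 10.76 ± 0.18 (SD), adjusted p 0.0015, Acat2 by 1.14 and the mevalonate kinase Mvk by 0.62. The fatty acid synthesis list did not pass (median 0.03, adjusted p = 0.762), with the malic enzyme Me1 (0.80) and Acss2 (0.70) risen and Elovl5 (−0.34) fallen of 17. Fatty acid oxidation did not pass either (3 of 37 risen, 7 risen and 1 fallen when adjusted over the list alone, median 0.03, adjusted p = 0.61). The sulfotransferase Sult2a6 (1.5), Acsm2 (1.43), the lipid droplet protein gene Cidea (1.21) and Orm1 (0.72) rose as well.

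Some cell cycle genes fell at 1000 mg/kg PPH in liver. Cdk1 (−1.98 ± 0.36, SE), Cdkn3 (−2.16) and Ccna2 (−1.76) were the 3 of 28 cell cycle members to fall, and 10 fell when adjusted over the list alone (median −0.42, adjusted p = 4.58e-11, and adjusted p = 0.17 with an estimated correlation). The treated means of Cdk1, Cdkn3 and Ccna2 (4.13, 3.98 and 2.73) and the vehicle mean of Ccna2 (4.48) lay under the filter value of 4.69, so the sizes of these falls are uncertain. Cyclin D1, Ccnd1, fell by 1.62 with an adjusted p of 0.00151. Of 14 male-biased genes that depend on growth hormone 3 fell, Igf1 (−0.28), Ghr (−0.42) and Igfals (−0.54), and 1 rose, against 4 and 1 when adjusted over the list alone (median −0.28, adjusted p = 0.00294, and adjusted p = 0.0707 with an estimated correlation). The gluconeogenesis list was lower (median −0.08, Pc the 1 of 13 to fall, adjusted p = 0.0141, and adjusted p = 0.17 with an estimated correlation). So were markers of macrophages (median −0.19, 0 of 12, 2 fallen when adjusted over the list alone, adjusted p = 0.000788, and adjusted p = 0.256 with an estimated correlation) and fibroblasts (median −0.14, 0 of 12, adjusted p = 0.0117, and adjusted p = 0.365 with an estimated correlation). Aldh1b1 (−1.30), Nrcam (−1.06), Apoa4 (−1.05), Nrep (−1.03), Olr59 (−0.94), Slpi (−0.90), the organic anion transporter gene Slc22a8 (−0.60) and Apoa1 (−0.28) fell too.

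At 500 mg/kg PPH 10 liver genes rose and 0 fell, led by Gstt3 (1.28, adjusted p = 0.00033) and Nqo1 (0.91, adjusted p = 0.00203), and Mif rose by 0.64. The count of 10 was 145 with all chemicals in 1 fit, 56 with array weights, 47 with the mean of probe sets and 3 when quantile normalized again. Gstt3 was the 1 gene to rise at 10 mg/kg (1.04, adjusted p = 0.00879), and its changes at 1, 10, 100, 500 and 1000 mg/kg were 0.84, 1.04, 0.71, 1.28 and 1.88. limma called 0 genes at 1 and 100 mg/kg, with 1202 and 1177 at an unadjusted p under 0.05. The trend rose in 111 genes and fell in 39, and its count of 150 was 21 with the difference between the 5' and 3' beta-actin control probe sets as a covariate. When the values were quantile normalized again the share risen moved from 69.4% to 55.4% at 1000 mg/kg (98 risen, 79 fallen) and from 74% to 59.7% for the trend (89 and 60). The count of 199 at 1000 mg/kg was 118, 121 and 65 without vehicle replicate PPH-202 and treated replicates PPH-237 and PPH-236, and the trend count of 150 was 79, 85, 88 and 53 without replicates PPH-202, PPH-237, PPH-232 and PPH-236. The count of 10 at 500 mg/kg was 6 without any 1 of vehicle replicates PPH-205, PPH-206, PPH-203 and PPH-208 and 4, 27, 5 and 2 without treated replicates PPH-229, PPH-230, PPH-232 and PPH-231. The count at 10 mg/kg was 0 without replicate PPH-218 or PPH-216 and 3 without PPH-219, and the counts of 0 at 1 and 100 mg/kg became 1 without replicate PPH-214 and vehicle replicate PPH-205. Of 47 named genes at 1000 mg/kg 28 passed in all 9 fits with 1 array left out, Gsta3, Gstt3, Nqo1 and Cdk1 among them, and 7 of 9 list calls did.

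In kidney, MCHM changed few single genes. At 500 mg/kg 2 of 11277 genes rose and 0 fell, and 61 were called with array weights. Dnase1, which encodes a secreted nuclease, rose from 10.7 ± 0.29 (SD, n = 5) to 11.58 ± 0.21 (SD, n = 4), adjusted p 0.0156, and Hpd, an enzyme of tyrosine breakdown, from 12.1 ± 0.07 to 12.59 ± 0.15 (SD), adjusted p 0.00561. The cell cycle list had 0 of 30 members fallen over all genes and 9 when adjusted over the list alone, with a median of −0.30 (adjusted p = 1.95e-17, and adjusted p = 0.0926 with an estimated correlation). Its mean per array was 6.35 ± 0.11 (SD, n = 5) in the vehicle kidneys and 6.04 ± 0.05 (SD, n = 4) at 500 mg/kg.

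Other lists in the kidneys at 500 mg/kg MCHM had small medians. Cholesterol synthesis was higher (median 0.14, 0 of 20, adjusted p = 0.000142, and adjusted p = 0.142 with an estimated correlation). Nrf2 targets (median −0.07, 0 of 23, 2 fallen when adjusted over the list alone, adjusted p = 0.000772, and adjusted p = 0.0926 with an estimated correlation) and phase II genes (median −0.08, 0 of 25, 1 risen and 5 fallen when adjusted over the list alone, adjusted p = 0.000383, and adjusted p = 0.0926 with an estimated correlation) were lower. So were lymphocyte markers (median −0.21, 0 of 7, adjusted p = 0.000942, and adjusted p = 0.0926 with an estimated correlation) and bile duct markers (median −0.18, 0 of 5, adjusted p = 0.0137, and adjusted p = 0.219 with an estimated correlation). The kidney injury list did not pass (median −0.04, adjusted p = 0.527), nor did the proximal tubule list (median 0.04, adjusted p = 0.851). Fat cell markers had a median change of 0.84 (0 of 6, adjusted p = 0.207), and their mean was 6.39 ± 1.49 (SD, n = 4) at 500 mg/kg against 5.77 ± 0.32 (SD, n = 5). A single kidney, replicate 42, was at 8.63, and the other 3 lay between 5.52 and 5.75, below the vehicle mean.

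The dose trend with MCHM in kidney rose in 7 genes and fell in 7, named after their values were seen. The count of 14 was 3 with the beta-actin difference as a covariate, 4 with the fat cell score as one, 2 without the 2 kidneys highest in fat cell markers and 45 with array weights. The risen genes included Dnase1 (0.14 log2 units per dose step), Hpd (0.06) and the fatty acid hydroxylase Cyp4a1 (0.09). The fallen ones included the mitotic genes Cdkn3 (−0.15) and Ccnb2 (−0.11), Akr1b8 (−0.13) and Cpt1a (−0.06), the carnitine transferase of fatty acid oxidation. limma called 0 genes at 0.1, 1, 10, 100 and 300 mg/kg, with 555, 1007, 699, 514 and 630 at an unadjusted p under 0.05. The count of 2 at 500 mg/kg was 1 without vehicle replicate 4 or 6, 0 without treated replicate 40, 4 without vehicle replicate 8 or treated replicate 43 and 8 without vehicle replicate 3 or treated replicate 41. The count at 10 mg/kg was 1 without replicate 22. The trend count of 14 was 6, 9, 9, 5, 8, 8, 6, 4, 30, 8, 8, 9 and 2 without replicates 4, 19, 31, 40, 6, 12, 8, 10, 15, 36, 16, 23 and 42. Of the 2 genes named at 500 mg/kg 0 passed in all 9 fits with 1 array left out.

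Crude MCHM in kidney gave 0 called genes at every dose among 11216 tested with limma. With all chemicals in 1 fit the counts were 17 at 0.1 mg/kg, 249 at 500 mg/kg and 27 in trend, and with array weights 238 at 500 mg/kg. From the lowest dose to the highest, 594, 813, 478, 358, 433 and 1406 genes had an unadjusted p under 0.05, as did 988 for the trend. Cholesterol synthesis was higher at 500 mg/kg (median 0.13, 0 of 20, 1 risen when adjusted over the list alone, adjusted p = 4.55e-05, and adjusted p = 0.713 with an estimated correlation), and macrophage markers were lower (median −0.37, 0 of 11, 3 fallen when adjusted over the list alone, adjusted p = 0.00155, and adjusted p = 0.713 with an estimated correlation). The cell cycle (median −0.21, adjusted p = 0.192) and kidney injury (median 0.10, adjusted p = 0.13) lists did not pass. The difference between the 5' and 3' beta-actin control probe sets, which falls with shorter or less complete RNA copies, was −2.56 ± 0.34 (SD, n = 3) in the vehicle kidneys, −2.73 ± 1.00 (SD, n = 3) at 300 mg/kg and −2.04 ± 0.12 (SD, n = 3) at 500 mg/kg. Without vehicle replicate Crude_MCHM-104 the counts at the 5 lower doses were, in order, 91, 55, 35, 2 and 29, and the trend count was 2. Of 11209 genes tested 1.84% were then called at 500 mg/kg, 81 of them lower. At 1 mg/kg the counts without replicates Crude_MCHM-119 and Crude_MCHM-120 were 3 and 7. The sets were small. In simulated data of this layout 47% of changes of 0.5 log2 units and 94% of 1 were found, which need not hold here.

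PPH at 1000 mg/kg had the clearest effect in kidney. Among 11264 genes 78 rose and 151 fell, and 85 changed by at least 1.5-fold. Genes of cell division were among the largest falls. Ccna2, cyclin A, fell from 5.65 ± 0.44 (SD, n = 5) to 3.67 ± 0.43 (SD, n = 4), adjusted p 2.7e-05, Cdk1 from 7.34 ± 0.33 to 5.73 ± 0.28 (SD), adjusted p 4.85e-05, and the proliferation marker Mki67 from 5.96 ± 0.19 to 4.41 ± 0.30 (SD), adjusted p 3.25e-05. The treated means of Ccna2 and Mki67 lay under the filter value of 4.66, so their falls are uncertain in size. Of 30 cell cycle genes 21 fell, and 26 when adjusted over the list alone (median −0.72, adjusted p = 1.61e-36, and adjusted p = 0.00421 with an estimated correlation, so that the call held).

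Single cell cycle genes were lower at lower doses of PPH in kidney without passing the test. Ccna2 was at −0.23, −0.61, −0.74 and −1.08, and Mki67 at −0.28, −0.44, −0.77 and −0.84, at 1, 10, 100 and 500 mg/kg. The mean of the cell cycle list per array was 6.45 ± 0.15, 6.37 ± 0.16, 6.24 ± 0.15, 6.13 ± 0.16, 5.99 ± 0.16 and 5.62 ± 0.14 (SD) from vehicle to 1000 mg/kg. At 500 mg/kg 19 of 30 members fell when adjusted over the list alone (median −0.39, adjusted p = 2.64e-29, and adjusted p = 0.02 with an estimated correlation). Cdkn3 (−1.92), Ccnb2 (−1.61), Prc1 (−1.54), Kif20a (−1.42) and Cks2 (−1.38) were further falls at 1000 mg/kg. Other genes that fell were the cyclooxygenase Ptgs2, from 6.57 ± 0.56 to 4.78 ± 0.35 (SD), adjusted p 0.000111, the matrix protein gene Mfap4 (−1.39), the macrophage marker Adgre1 (−0.80), complement C3 (−0.64) and the glucose transporter Slc2a2 (−0.53).

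**Figure D4:**
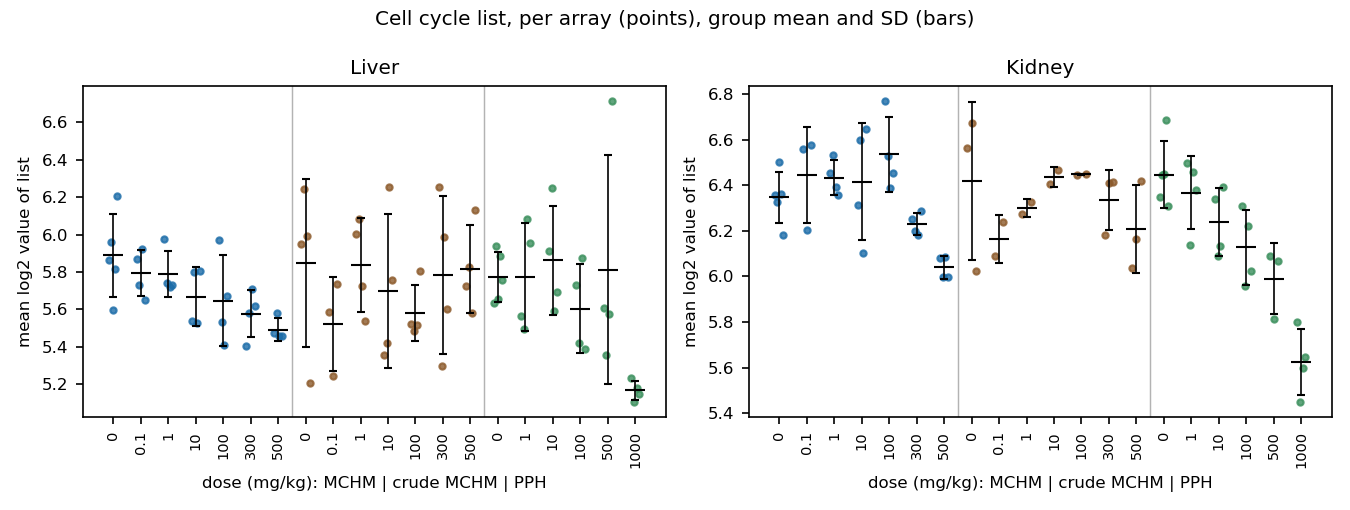
Mean log2 value of the cell cycle list per array (points) with the group mean and SD (bars), at each dose in mg/kg of MCHM, crude MCHM and PPH, in liver and kidney. With PPH in kidney the group mean went from 6.45 in the vehicle group to 5.62 at 1000 mg/kg, where the 4 arrays lay between 5.45 and 5.80.

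Some conjugation and fatty acid oxidation genes rose in kidney with PPH. Gstm1 rose 2.31-fold, from 7.77 ± 0.26 to 8.97 ± 0.22 (SD), adjusted p 0.000418, Gsta3 by 0.91 and Gstm2 by 0.70. They were among 5 of 25 phase II genes to rise, against 13 risen and 1 fallen when adjusted over the list alone (median 0.26, adjusted p = 2.13e-11, and adjusted p = 0.00248 with an estimated correlation, which held). Of 35 fatty acid oxidation genes 5 rose, and 11 when adjusted over the list alone, with Ehhadh from 10.08 ± 0.03 to 10.78 ± 0.21 (SD), Decr1 at 0.52 and Cyp4a3 at 0.40 (median 0.10, adjusted p = 8.36e-07, and adjusted p = 0.187 with an estimated correlation). At 500 mg/kg the phase II (median 0.17, 0 of 25, 3 risen when adjusted over the list alone, adjusted p = 1.06e-06, and adjusted p = 0.02 with an estimated correlation) and fatty acid oxidation lists (median 0.15, 0 of 35, 8 risen when adjusted over the list alone, adjusted p = 2.48e-10, and adjusted p = 0.0449 with an estimated correlation) were already higher. Dmrtc1c1 (1.31), Gtpbp4 (1.29), the vitamin E transfer protein gene Ttpa (0.96), Bhmt (0.96), Fam13c (0.88), Sult1a1 (0.83), the P450 gene Cyp2e1 (0.76), Cracdl (0.72) and the gluconeogenic enzyme Pck1 (0.52) rose as well.

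Smaller list changes at 1000 mg/kg PPH in kidney were lost with an estimated correlation. Nrf2 targets (median 0.05, 2 of 23 risen, 4 risen and 2 fallen when adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.236 with an estimated correlation), CAR and PXR targets (median 0.11, 0 of 10, adjusted p = 0.0419, and adjusted p = 0.299 with an estimated correlation), bile acid genes (median 0.14, Amacr the 1 of 15 to rise, adjusted p = 0.0419, and adjusted p = 0.236 with an estimated correlation) and dehydrogenases (median 0.06, Aldh1l1 the 1 of 13 to rise, adjusted p = 0.0419, and adjusted p = 0.436 with an estimated correlation) were higher. Without the filter on low values the dehydrogenase median was −0.02. Macrophage (median −0.15, Adgre1 the 1 of 11 to fall, adjusted p = 0.0117, and adjusted p = 0.33 with an estimated correlation) and fibroblast markers (median −0.10, 0 of 11, 4 fallen when adjusted over the list alone, adjusted p = 0.0419, and adjusted p = 0.47 with an estimated correlation) were lower. The kidney injury (median −0.06, adjusted p = 0.82), p53 (median −0.06, adjusted p = 0.457) and proximal tubule lists (median 0.04, 0 of 23, adjusted p = 0.0728) did not pass. The beta-actin difference was −2.44 ± 0.08 (SD, n = 4) at 1000 mg/kg and −2.70 ± 0.33 (SD, n = 5) in the vehicle kidneys.

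limma called 0 kidney genes at 1, 10, 100 and 500 mg/kg PPH, with 324, 927, 834 and 565 at an unadjusted p under 0.05. The trend rose in 51 genes and fell in 127. The count at 1000 mg/kg was between 97 and 152 without any 1 of vehicle replicates PPH-205, PPH-206 and PPH-203 and treated replicates PPH-236 and PPH-234, lowest without PPH-236 and highest without PPH-203, and 362 without vehicle replicate PPH-208. The trend count of 178 was 118 and 111 without replicates PPH-205 and PPH-236, and the count at 100 mg/kg was 2 without vehicle replicate PPH-208. Of 32 named genes 18 passed in all 9 fits with 1 array left out, Ccna2, Cdk1, Mki67, Ptgs2, Gstm1 and Ehhadh among them, and 3 of 9 list calls did.

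The alicyclic alcohol MCHM and the phenyl glycol ether PPH were compared at the 4 doses they shared. In liver at 500 mg/kg 1 gene was higher with MCHM and 3 were lower, each with an adjusted p of 0.0471. Mif, a cytokine gene, differed by −0.65 (95% interval −0.93 to −0.37), with −0.01 for MCHM and 0.64 for PPH. The changes in the other 3, Lactb2, C5l1 and Thyn1, differed by 0.46 (0.26 to 0.66), −0.80 (−1.14 to −0.46) and −0.60 (−0.84 to −0.36). Gstt3 (−1.03, adjusted p = 0.166) and Nqo1 (−0.87, adjusted p = 0.116) did not pass this test. The count of 4 was 0 without the filter on low values and also 0 with only these chemicals in the fit. For 75.5% of genes the interval lay within 1.5-fold. At 10 mg/kg Tubb2a, a tubulin gene named after its values were seen, differed by −1.18 (interval −1.62 to −0.74, adjusted p = 0.0138, count 0 with only these chemicals in the fit). At 1 and 100 mg/kg limma called 0 genes, with 855 and 993 at an unadjusted p under 0.05. The count of 4 at 500 mg/kg was 14, 9, 2 and 1 without replicates 41, PPH-232, PPH-229 and PPH-208 and 0 without any 1 of replicates 4, 40, 8, 3, 43, 42, 7, PPH-205, PPH-230, PPH-206 and PPH-231. At 10 mg/kg the count of 1 was 9 and 8 without replicates 25 and PPH-216, 4 without 8 or PPH-205, 2 without PPH-218 or PPH-203 and 0 without 6, 26, 23, PPH-219, PPH-217 or PPH-208. The count at 1 mg/kg was 14 without replicate 15 and 1 without 8, 3 or PPH-203.

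Crude MCHM and PPH differed in 0 liver genes with limma at 1, 10, 100 and 500 mg/kg, with 591, 705, 791 and 879 at an unadjusted p under 0.05. The interval lay within 1.5-fold for 74.6% of genes at 500 mg/kg. The count was 1 at 10 mg/kg without replicate Crude_MCHM-126, and 6, 4 and 1 at 500 mg/kg without replicates PPH-232, Crude_MCHM-104 and PPH-205.

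In kidney at 500 mg/kg MCHM and crude MCHM differed in 3 genes. Vkorc1l1, a relative of the vitamin K reductase, was higher with MCHM by 0.75 (95% interval 0.45 to 1.04, adjusted p = 0.0269) and the repressor gene Erf by 0.55 (0.32 to 0.78, adjusted p = 0.0448). The histone demethylase gene Kdm5a was lower by −1.38 (−1.90 to −0.85, adjusted p = 0.0269). With only these chemicals in the fit the count was 0. The changes were unrelated in size across genes, which are not independent replicates (r = −0.012, rho = 0.018), and 70.2% of intervals lay within 1.5-fold. At 0.1, 1, 10, 100 and 300 mg/kg limma called 0 genes, with 722, 1166, 457, 699 and 453 at an unadjusted p under 0.05. The count of 3 was 0 without any 1 of replicates 40, 6, 42, Crude_MCHM-106, Crude_MCHM-143, Crude_MCHM-105 and Crude_MCHM-144, 1 without 43 or 5 and 5 without Crude_MCHM-139. Without vehicle replicate Crude_MCHM-104 the counts at the 6 doses ranged from 31 at 10 and 300 mg/kg to 383 at 500 mg/kg. At 1 mg/kg the count was 16 without replicate Crude_MCHM-120 and 1 without Crude_MCHM-119 or 3, and at 100 mg/kg it was 1 without Crude_MCHM-129.

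Between crude MCHM and PPH in kidney 5 genes were higher with crude MCHM and 6 lower at 500 mg/kg. Ccdc127 (1.60), Kdm5a (1.36), Wbp4 (0.98), Clip1 (0.86) and Pa2g4 (0.82) were higher. The pyruvate carboxylase Pc (−0.91), the thyroid hormone deiodinase Dio1 (−0.85), Tbc1d10a (−0.76), Ptgr3 (−0.73) and Sh3tc1 (−0.66) were lower, with adjusted p between 0.0445 and 0.0478. The count of 11 was 0 without the filter, 0 with the mean of probe sets and 1 with only these chemicals in the fit. MCHM and PPH differed in 0 kidney genes with limma at 1, 10, 100 and 500 mg/kg (751, 1123, 942 and 762 at an unadjusted p under 0.05), with 79.6% of intervals within 1.5-fold at 500 mg/kg. Crude MCHM and PPH differed in 0 with limma at 1, 10 and 100 mg/kg (698, 737 and 472 at an unadjusted p under 0.05). The crude MCHM and PPH count of 11 was 0 without any 1 of replicates Crude_MCHM-106, Crude_MCHM-105, Crude_MCHM-144, PPH-229, PPH-205, PPH-230 and PPH-208, 1 without Crude_MCHM-143 or PPH-203, 2 without PPH-232 and 3 without Crude_MCHM-139. Without vehicle replicate Crude_MCHM-104 the counts at 1, 10, 100 and 500 mg/kg were 69, 59, 15 and 211, with 11 at 1 mg/kg without Crude_MCHM-120 and 1 at 100 mg/kg without PPH-208. The MCHM and PPH counts were 9 and 1 at 10 mg/kg without replicates 22 and 3, 2 and 1 at 100 mg/kg without PPH-202 and PPH-208, and 2 at 500 mg/kg without 3 and 1 without 40, 5 or PPH-202.

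The liver and kidney responses were compared within each chemical at 500 mg/kg, in fits that did not pair the tissues by replicate number. With the number as a block the counts of 9, 8 and 2 genes for MCHM, crude MCHM and PPH were 18, 49 and 2. With MCHM 8 genes changed more in the positive direction in liver and 1 less, among them Acly (difference 1.08, liver 0.90 and kidney −0.17), Me1 (0.89), Sectm1b (0.86), Hes6 (0.86) and Asap2 (0.70). Tfpi, an inhibitor of clotting, differed by −0.65. With crude MCHM 6 differed one way and 2 the other, among them Ccdc85c (1.12), Hes6 (1.05), the carboxylate carrier gene Slc16a13 (1.04), Dgkd (0.77) and Pecr (0.54), and Trps1 (−1.55) and Kdm5a (−1.44). With PPH, Gstt3 was at 1.28 in liver and 0.25 in kidney, a difference of 1.03 (95% interval 0.67 to 1.40, adjusted p = 0.0119). Cks2 was at 0.33 and −0.84, a difference of 1.17 (0.72 to 1.62, adjusted p = 0.0324). The MCHM count of 9 was 18, 1, 3 and 4 without livers 41, 43, 42 and 7 and 3, 5, 20 and 0 without kidneys 4, 40, 3 and 42. The crude MCHM count of 8 was 5, 0, 4, 1 and 25 without livers Crude_MCHM-140, Crude_MCHM-106, Crude_MCHM-108, Crude_MCHM-144 and Crude_MCHM-104, 0 without kidney Crude_MCHM-106, Crude_MCHM-105 or Crude_MCHM-144, and 2, 322 and 51 without kidneys Crude_MCHM-143, Crude_MCHM-104 and Crude_MCHM-139. The PPH count of 2 was 1 without liver PPH-202, PPH-205, PPH-206, PPH-208 or PPH-231 or kidney PPH-206, PPH-203 or PPH-232, 0 without liver PPH-232 or kidney PPH-230 and 3 without kidney PPH-202.

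The vehicle groups, which received corn oil alone, were compared to see whether the chemical sets shared a baseline. In liver 1327 genes differed between the MCHM and crude MCHM vehicle groups (1042 higher and 285 lower with MCHM), 2019 between those of MCHM and PPH (1174 and 845) and 296 between those of crude MCHM and PPH (152 of them lower with crude MCHM). In kidney the counts of the first 2 pairs were 2563 (627 and 1936) and 3625 (1115 and 2510), and between crude MCHM and PPH 42 genes were higher and 160 lower. The beta-actin difference was −1.99 ± 0.14, −1.25 ± 0.05 and −1.19 ± 0.07 (SD) in the vehicle livers of the MCHM, crude MCHM and PPH sets, and −1.29 ± 0.02, −2.56 ± 0.34 and −2.70 ± 0.33 in the vehicle kidneys. By design each treated group was compared with the vehicle group of its own set. The liver counts were 804 (MCHM and crude MCHM) without replicate Crude_MCHM-106, and 192, 167 and 191 (crude MCHM and PPH) without replicates Crude_MCHM-106, Crude_MCHM-108 and Crude_MCHM-104. The kidney counts were 1397 and 1095 (MCHM and crude MCHM) without Crude_MCHM-106 and Crude_MCHM-105, and 60, 35 and 382 (crude MCHM and PPH) without Crude_MCHM-106, Crude_MCHM-105 and Crude_MCHM-104.

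**Figure D5:**
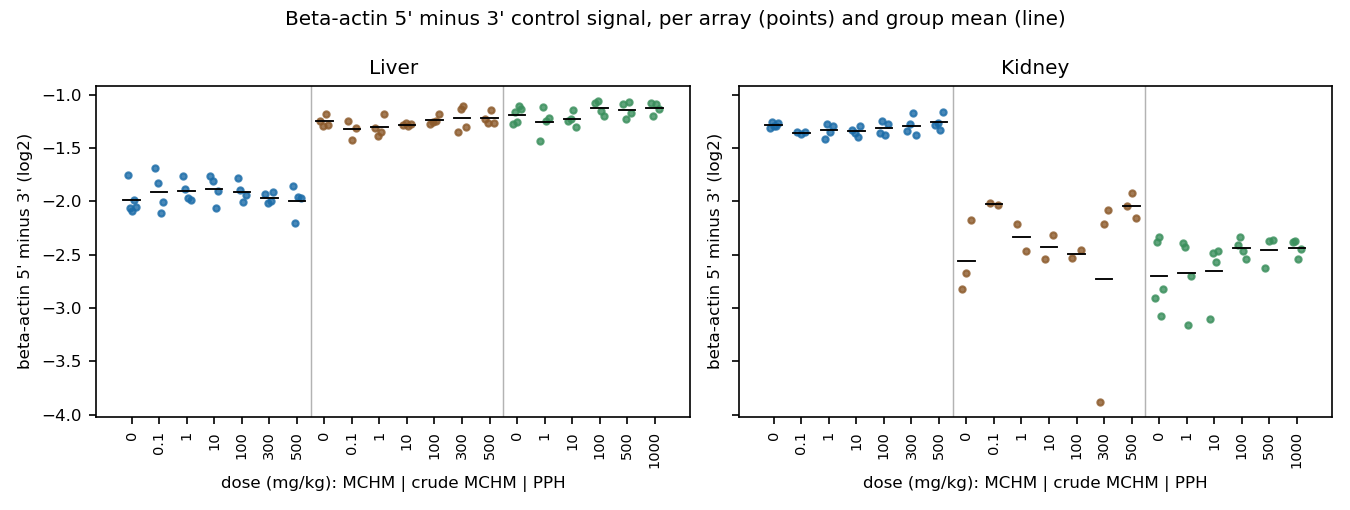
Difference between the 5' and 3' beta-actin control probe sets in log2 units per array (points) with the group mean (line), at each dose in mg/kg of MCHM, crude MCHM and PPH, in liver and kidney. The mean of the vehicle kidneys was −1.29 in the MCHM set, −2.56 in the crude MCHM set and −2.70 in the PPH set.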

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

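The tests of the spiked controls, of other cell types, of fat on the kidneys and of whether replicate Crude_MCHM-104 stood apart, and the splits of liver at 500 mg/kg MCHM and of the difference between MCHM and crude MCHM in liver at 300 mg/kg, were chosen after the result was seen.

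Corn oil groups that should share a baseline differed between the chemical sets, by up to 3625 genes. An animal difference shared by both tissues stays open. The MCHM minus PPH vehicle differences of liver and kidney had r = −0.321 across genes, which are not independent replicates. Of 1032 genes called in both 44 had the same sign. As the beta-actin difference reversed too, r cannot decide. Spiked-in controls differed between sets (over 2 pooled SDs for 19.1% to 100% of 42 probe sets in the 6 pairs), so labelling or hybridization is a candidate. RNA coverage stays open too, because each gene's slope on the beta-actin difference inside dosed groups correlated with the vehicle difference at r = 0.188 in liver and 0.484 in kidney for MCHM and PPH, and, signed by the beta-actin difference of the groups, from 0.0766 to 0.13 in liver and from −0.1 to 0.522 in kidney for the other pairs. The chemical sets and any processing batch cannot be told apart, and no biological explanation other than a difference between animals was tested.

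Cell cycle genes were lower in kidney at 1000 mg/kg PPH (median −0.72). Fewer cells of another type stay open: marker medians fell less (lowest −0.15, macrophage) but can miss a small share. RNA coverage is argued against by a median of −0.65, with 20 genes fallen, when the beta-actin difference was a covariate, and fat on the kidneys by a median of −0.71, also with 20 fallen, when the fat cell score was one. A slowing of cell division by PPH may remain as a hypothesis found on these data, and division itself and the cells concerned were not tested.

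With crude MCHM in kidney limma called 0 genes at 500 mg/kg with all 3 vehicle kidneys and 1.84% of 11209 (81 of them fallen) without vehicle replicate Crude_MCHM-104. Whether Crude_MCHM-104 itself stands apart stays open: its median correlation with the other kidneys ranked 3 of 17 from the highest, but these lay close together (0.987 to 0.994), and its cell cycle mean was the lowest of the 17 (6.02, against 6.67 and 6.56 in the other vehicle kidneys). RNA coverage of vehicle replicates Crude_MCHM-105 and Crude_MCHM-106, whose beta-actin differences were −2.68 and −2.82 against −2.17 for Crude_MCHM-104, is a candidate explanation, since the count was 93 when that difference was a covariate. Of genes that rose 82.4% had a positive slope on that difference in 14 treated kidneys (all genes 37.9%). Of those that fell 72.8% had a negative one (62.1%). Crude_MCHM-134 (−3.877) dominates these slopes, so they cannot decide. An effect of crude MCHM on the kidney stays open as the biological explanation, which these 3 vehicle kidneys leave untested.

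Other splits of the same samples are given only as whether chance can be excluded, with the real count and the highest of the other splits. Chance was excluded (at most 4 of 100 splits with as many genes) for liver MCHM at 300 mg/kg (3, highest other 1), at 500 mg/kg (58, highest other 1) and in trend (270, highest other 6), and for liver PPH at 500 mg/kg (10, highest other 1), at 1000 mg/kg (199, highest other 47) and in trend (150, highest other 2). It was also excluded for liver crude MCHM at 300 and 500 mg/kg (1 of 35 splits each, 115 with a highest other of 2, and 77 with 10) and in trend (157 risen and 61 fallen, highest other 41 in all). In kidney it was excluded for the trends of MCHM (14, highest other 2) and PPH (178, highest other 0), for MCHM at 500 mg/kg (3 of 100 splits, real count 2, highest other 226) and for PPH at 1000 mg/kg (2 of 100 splits, 78 risen and 151 fallen, highest other 240 in all). The split with 226 genes was the real one with vehicle replicate 3 and treated replicate 41 exchanged, so it is not independent of dose. Chance was excluded for the vehicle comparisons, in liver (1327, 2019 and 296, highest others 604, 440 and 1.86% of the 11624 genes tested) and in kidney (2563 and 3625, highest others 1041 and 1519, and 42 higher with 160 lower, highest other 201 in all). For differences between chemicals or tissues the splits exchanged dose and vehicle labels within each chemical or tissue. They ask whether either had any dose effect, so a low share cannot exclude chance for the difference itself. The share was 4 of 100 splits for liver MCHM against PPH at 500 mg/kg (real count 4, highest other 78). For the tissue difference of MCHM it was 2 of 100 (real count 9, highest other 35). It was 2 for crude MCHM (real count 8, highest other 10) and 3 for PPH (real count 2, highest other 4). Livers and kidneys were exchanged apart, without regard to shared replicate numbers.

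Chance was not excluded for liver PPH at 10 mg/kg (7 of 100 splits, real count 1, highest other 3), liver MCHM against PPH at 10 mg/kg (7, real count 1, highest other 1), kidney MCHM against crude MCHM at 500 mg/kg (12, real count 3, highest other 241) and kidney crude MCHM against PPH at 500 mg/kg (7, real count 11, highest other 84). A real count of 0 excludes no chance, since every split (100 of 100, 35 of 35 or 56 of 56) gives as many. This held for liver MCHM at 0.1 to 100 mg/kg (highest others 1, 1, 4 and 1), liver crude MCHM at 0.1 to 100 mg/kg (1, 1, 0 and 1), liver PPH at 1 and 100 mg/kg (3 and 3), kidney MCHM at 0.1 to 300 mg/kg (1, 95, 1, 2 and 2) and kidney PPH at 1 to 500 mg/kg (19, 1, 15 and 1). It held too for liver MCHM against crude MCHM at 0.1 to 500 mg/kg (1, 1, 2, 0, 10 and 71), liver MCHM against PPH at 1 and 100 mg/kg (3 and 2), liver crude MCHM against PPH at 1 to 500 mg/kg (1, 1, 84 and 53), kidney MCHM against crude MCHM at 300 mg/kg (974) and kidney MCHM against PPH at 1 to 500 mg/kg (1, 4, 44 and 1). The cause of those from 15 upwards was not tested. For kidney crude MCHM at 300 and 500 mg/kg the 10 splits are too few for a share under 0.05 (real counts 0 and 0, highest others 549 and 2), and the split with 549 genes set replicates Crude_MCHM-106, Crude_MCHM-134 and Crude_MCHM-105 together, 3 kidneys with a low beta-actin difference.

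A single array lay far from the rest of its group for 21 of 274 groups tested among named genes (7.66%), where chance gives about 1 in 20. In liver with MCHM these were Gpt in 500 mg/kg replicate 41 (10.06, others 9.66 to 9.72), Spmip11 in vehicle replicate 4 (5.93, others 5.36 to 5.43) and Nusap1 in vehicle replicate 7 (6.83, others 6.29 to 6.42). In liver with crude MCHM they were Ehhadh in vehicle replicate Crude_MCHM-104 (11.25, others 10.68 to 10.76) and in 500 mg/kg replicate Crude_MCHM-144 (11.81, others 11.51 to 11.55). In 500 mg/kg replicate Crude_MCHM-140 they were Decr2 (10.59, others 10.72 to 10.73) and Gstk1 (11.38, others 11.51 to 11.53). Among the PPH vehicle livers they were Cidea (6.52, others 7.43 to 7.67) and Slc17a3 (9.14, others 9.44 to 9.48) in replicate PPH-202, Acat2 (8.19, others 8.89 to 9.17) in replicate PPH-203. In replicate PPH-205 they were Ccna2 (5, others 4.29 to 4.46), Slpi (9.69, others 9.02 to 9.19) and Apoa1 (13.58, others 13.31 to 13.38). At 1000 mg/kg PPH in liver Mvk (9.42, others 9 to 9.05) and Igf1 (12.93, others 12.97) stood apart in replicate PPH-236, and Slc27a5 (12.59, others 12.79 to 12.81) in replicate PPH-237. In kidney they were Dnase1 in 500 mg/kg MCHM replicate 43 (11.89, others 11.45 to 11.51), Ccnb2 in PPH vehicle replicate PPH-208 (6.33, others 6.66 to 6.80). At 1000 mg/kg PPH they were Gtpbp4 in replicate PPH-237 (9.56, others 8.08 to 8.26), Cdkn3 in replicate PPH-236 (4.68, others 5.50 to 5.53) and Slc2a2 in replicate PPH-234 (10.17, others 9.60 to 9.66).

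Tests of differences between chemicals or tissues called genes, with chance not excluded. In liver MCHM and PPH had 1 at 10 mg/kg (Tubb2a) and 4 at 500 mg/kg (Mif among them). In kidney at 500 mg/kg MCHM and crude MCHM had 3 (Kdm5a among them), and crude MCHM and PPH 11. Between liver and kidney at 500 mg/kg MCHM had 9 (Acly among them), crude MCHM 8 (Trps1 among them) and PPH 2 (Gstt3 and Cks2).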

How the results depend on the processing

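The tests with the beta-actin covariate, the fat cell covariate, the kidneys left out for either measure and the column included were chosen after the result was seen. The naming rule made reversal unlikely. Of the comparisons of named genes with an alternative, 0 reversed, and those that lost their call numbered 18 without a filter, 12 with the mean of probe sets, 5 with quantile normalization, 5 with array weights, 12 with all chemicals in 1 fit and 16 with the beta-actin covariate. In the same order 0, 5, 5, 46, 28 and 2 gained one. With 1 array left out 5656 of such comparisons kept their call or lack of one, 355 lost it and 48 gained it. An estimated correlation ended most list calls (55) and left 180 mostly uncalled lists the same. The correlation of MCHM and crude MCHM changes, 0.506 in liver and −0.012 in kidney, was between 0.449 and 0.51 and between −0.009 and −0.007 with no filter, the mean of probe sets or quantile normalization, the alternatives run for it. Signal over background limits genes near the filter value. Except where fewer arrays or genes entered by construction, the cause was not tested.

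With array weights the counts were, in liver, 1 at 10 mg/kg MCHM and 425 in trend, and 56 at 500 mg/kg PPH. In kidney they were 61 at 500 mg/kg MCHM and 45 in trend. Differences in liver were 1 for MCHM against crude MCHM at 1 mg/kg, 1, 7 and 23 for MCHM against PPH at 1, 10 and 500 mg/kg, 4 for crude MCHM against PPH at 500 mg/kg and 477 between their vehicles. In kidney they were 15 and 608 for MCHM against crude MCHM at 1 and 500 mg/kg, 2, 22, 1 and 19 for MCHM against PPH at 1, 10, 100 and 500 mg/kg, 17, 15 and 288 for crude MCHM against PPH at 1, 10 and 500 mg/kg and 378 between their vehicles. Tissue differences were 61 for MCHM and 508 for crude MCHM.

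With all chemicals in 1 fit the counts in liver were 43 at 300 mg/kg crude MCHM, and 8, 5, 145 and 348 at 1, 10, 500 and 1000 mg/kg PPH with 289 in trend. In kidney they were 1 and 5 at 10 and 500 mg/kg MCHM with 35 in trend, and 17 at 0.1 mg/kg crude MCHM with 27 in trend. With only the chemicals compared in the fit they were 0 for MCHM against PPH in liver at 10 and at 500 mg/kg, 1 for crude MCHM against PPH in liver at 100 mg/kg, 0 for MCHM against crude MCHM in kidney at 500 mg/kg, 2 and 1 for MCHM against PPH in kidney at 100 and 500 mg/kg and 1 for crude MCHM against PPH in kidney at 500 mg/kg.

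With no filter, which tests more genes, the counts were 55 at 300 mg/kg crude MCHM in liver, 1 at 10 mg/kg MCHM in kidney and 8 in trend, 0 for MCHM against PPH in liver, 5 for MCHM against crude MCHM in kidney and 0 for crude MCHM against PPH in kidney, each at 500 mg/kg. The median of the dehydrogenase list in kidney at 1000 mg/kg PPH reversed to −0.018. With quantile normalization they were 61 at 300 mg/kg crude MCHM and 3 at 500 mg/kg PPH in liver, 3 at 300 mg/kg MCHM in kidney and 32 in trend. They were also 1 and 4 for MCHM against PPH in liver at 1 and 10 mg/kg, 1 for crude MCHM against PPH in liver at 500 mg/kg, 5 for MCHM against crude MCHM and 1 for MCHM against PPH in kidney at 500 mg/kg, 1 and 41 for crude MCHM against PPH in kidney at 100 and 500 mg/kg and 1 for the tissue difference of PPH. With the mean of probe sets they were 47 at 500 mg/kg PPH in liver, 4 at 300 mg/kg MCHM in kidney, 1 and 0 for crude MCHM against PPH at 500 mg/kg in liver and kidney, and 5 and 5 for the tissue differences of MCHM and crude MCHM.

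With the beta-actin covariate the counts were 61 at 300 mg/kg crude MCHM in liver, 1 and 6 at 1 and 500 mg/kg PPH in liver and 21 in trend, and 3 for the trend of MCHM in kidney. With the fat cell covariate they were 1 at 10 mg/kg MCHM in kidney and 4 in trend, and without the 2 kidneys highest in fat cell markers 1 at 10 mg/kg, 0 at 500 mg/kg and 2 in trend. With the column included, that trend count was 0 as deposited and 24 after moving it by 1 position. Without the 3 kidneys lowest in the beta-actin difference, the cell cycle median at 500 mg/kg crude MCHM reversed from −0.21 to 0.168. Reversed medians with 1 array left out were those of the male-biased list in liver at 500 mg/kg PPH (−0.048, from −0.1 without replicate PPH-230 to 0.009 without PPH-229, and 0.002 without vehicle replicate PPH-203), of the cell cycle list there (0.069, from −0.234 without replicate PPH-231 to 0.199 without PPH-230) and of the interferon list in kidney at 500 mg/kg MCHM (0.043, from −0.203 without replicate 43 to 0.113 without 41).

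With 1 array left out, 20 counts of 0 stayed at 0. Other counts in liver ranged from 0 to 1, 0 to 4 and 158 to 310 for MCHM at 10 and 300 mg/kg and in trend. For crude MCHM they ranged over 0 to 5 and 3 to 83 at 100 and 300 mg/kg. For PPH they ranged over 0 to 1, 0 to 3, 0 to 1, 2 to 27, 65 to 183 and 53 to 164 from 1 to 1000 mg/kg and in trend. In kidney they ranged from 0 to 1, 0 to 8 and 2 to 30 for MCHM at 10 and 500 mg/kg and in trend. Kidney counts with crude MCHM ranged over 0 to 91, 0 to 55, 0 to 35, 0 to 2, 0 to 29 and 0 to 2 from 0.1 to 300 mg/kg and in trend. With PPH they ranged over 0 to 2 and 97 to 362 at 100 and 1000 mg/kg. Differences in liver ranged from 0 to 1 for MCHM against crude MCHM at 1, 10 and 300 mg/kg, 0 to 14, 0 to 9 and 0 to 14 for MCHM against PPH at 1, 10 and 500 mg/kg, and 0 to 1 and 0 to 6 for crude MCHM against PPH at 10 and 500 mg/kg. In kidney they ranged from 0 to 73, 0 to 31, 0 to 57, 0 to 31 and 0 to 383 for MCHM against crude MCHM from 1 to 500 mg/kg, 0 to 9, 0 to 2 and 0 to 2 for MCHM against PPH at 10, 100 and 500 mg/kg, and 0 to 69, 0 to 59, 0 to 15 and 0 to 211 for crude MCHM against PPH. Vehicle counts ranged from 804 to 1255, 1673 to 1973 and 167 to 360 in liver and from 1095 to 2988, 3027 to 3541 and 35 to 382 in kidney, and tissue counts from 0 to 20, 0 to 322 and 0 to 3. Where 1 of the 2 kidneys of a crude MCHM group was left out, the lone sample was assumed to vary like the other groups.

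For 6 results the genes called are given as a percent of the genes tested. In liver at 500 mg/kg MCHM it was 0.512%, and 1.53% with array weights, 1.15% with all chemicals in 1 fit and 0.168% to 0.477% with 1 array left out. In liver at 500 mg/kg crude MCHM it was 0.675%, and 1.7%, 1.14% and 0.202% to 1.17% in the same order. The trend of crude MCHM in liver had 1.91%, and 3.27% with array weights, 0.978% with no filter, 0.965% with the beta-actin covariate and 0.737% to 2.26% with 1 array left out. In kidney at 500 mg/kg crude MCHM it was 0%, and 2.12% with array weights, 2.17% with all chemicals in 1 fit and 0% to 1.84% with 1 array left out. The trend of PPH in kidney had 1.58%, and 0.986% to 2.08% with 1 array left out. For MCHM against crude MCHM in kidney at 0.1 mg/kg it was 0%, and 0.548% with array weights and 0% to 0.922% with 1 array left out.

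Whether a replicate number in both tissues names an animal was unstated. With it as a block tissue counts were 18, 49 and 2 for MCHM, crude MCHM and PPH. They included all 9, 8 and 2 genes called without it. Block correlations were 0.0844, 0.0556 and 0.0873. With group means removed, arrays sharing a number had median r 0.127, 0.0885 and 0.124 (other pairs −0.0372, −0.0609 and −0.0422). The best match shared it in 26 of 27, 15 of 16 and 21 of 22 cases.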

Other observations

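The test of Cish and Bcl6 was chosen after the result was seen.

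List changes at other doses showed some groups not described so far. In liver at 300 mg/kg crude MCHM the fatty acid synthesis list was higher, with 3 of 17 members risen (median 0.60, adjusted p = 4.38e-09, and adjusted p = 0.193 with an estimated correlation). The list of the endoplasmic reticulum stress and amino acid response, which includes chaperones and serine synthesis enzymes, was higher in liver at 0.1, 10, 100 and 300 mg/kg crude MCHM (medians 0.20, 0.25, 0.20 and 0.27, adjusted p = 0.0124, 5.1e-05, 0.00549 and 0.00396, and adjusted p = 0.591, 0.465, 0.563 and 0.469 with an estimated correlation). At 100 and 300 mg/kg MCHM the liver cholesterol list was higher (medians 0.18 and 0.21, adjusted p = 5.64e-06 and 4.74e-08, and adjusted p = 0.94 and 0.403 with an estimated correlation) and the cell cycle list lower (medians −0.22 and −0.25, adjusted p = 3.06e-08 and 4.74e-08, and adjusted p = 0.516 and 0.305 with an estimated correlation). Lymphocyte markers were higher in liver at 0.1 mg/kg MCHM (median 0.23, adjusted p = 1.57e-06, and adjusted p = 0.00276 with an estimated correlation). Gluconeogenesis genes were lower in liver at 1 mg/kg PPH (median −0.19, adjusted p = 4.47e-06, and adjusted p = 0.0347 with an estimated correlation).

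In kidney the cell cycle list was lower at 10 and 100 mg/kg PPH (medians −0.16 and −0.28, adjusted p = 3.26e-05 and 1.02e-12, and adjusted p = 0.375 and 0.248 with an estimated correlation) and higher at 100 mg/kg MCHM (median 0.22, adjusted p = 2.88e-07, and adjusted p = 0.795 with an estimated correlation). Interferon response genes were lower at 300 mg/kg crude MCHM (median −0.31, adjusted p = 6.61e-10, and adjusted p = 0.333 with an estimated correlation). Fat cell markers were higher in kidney at 300 mg/kg MCHM (median 1.08, adjusted p = 0.00684, and adjusted p = 0.565 with an estimated correlation), where 1 kidney, replicate 36, had a mean of 9.585 and the other 3 lay between 5.57 and 5.64, below the vehicle mean of 5.77. They were also higher at 10 mg/kg PPH (median 0.93, adjusted p = 3.26e-05, and adjusted p = 0.187 with an estimated correlation). At 10 mg/kg PPH in kidney fatty acid synthesis genes (median 0.23, adjusted p = 3.26e-05, and adjusted p = 0.0432 with an estimated correlation) and hepatocyte markers (median 0.60, adjusted p = 0.00148, and adjusted p = 0.0432 with an estimated correlation) were higher as well.

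Cish and Bcl6, which growth hormone induces and represses in liver, varied between livers (Cish from 4.79 to 8.14 and Bcl6 from 5.3 to 10.63 log2 units over all groups of the MCHM set). A hypothesis is that growth hormone pulses may have been at different stages when the livers were taken, which predicts a negative correlation within groups. After removing group means, r was −0.493 in the MCHM set (n = 29, permutation p = 0.007, adjusted p = 0.021, rho = −0.381 with permutation p = 0.04), −0.259 in the crude MCHM set (n = 27, permutation p = 0.2, adjusted p = 0.2, rho = −0.269 with permutation p = 0.2) and −0.281 in the PPH set (n = 25, permutation p = 0.2, adjusted p = 0.2, rho = −0.231 with permutation p = 0.3). Without the 2 livers farthest from the median of Cish, r was −0.441, −0.200 and −0.368. These 3 relations leave the hypothesis open, since the weakest, −0.259, missed the threshold.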
